A study of Mus musculus with 10 samples.

How the data were processed

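The samples were RN2 cells (mouse leukaemia with MLL-AF9 and mutant NRAS) overexpressing murine IKZF2, and each was a CUT&RUN sample sequenced as paired ends, per the labels' protocols. Groups came from the sample titles: 6 samples with the anti-IKZF2 antibody (3 libraries, 2 technical replicates each) and 4 with a control antibody (2 libraries, 2 technical replicates each). The control antibody samples were not analysed here.

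For each of the 6 samples the deposited table gave a raw read count for each region of a set common to all samples, with no normalization. Region names call the set combined, and region numbers ran to 153953 with 2820 unused. Coordinates are in mm10, and Bowtie2 2.3.3.1 and MACS2 are named, per the submitters' processing notes. The role of each tool, the MACS2 version, the peak threshold and which samples entered the calls are not given in the sources used here. Whether region starts count from 0 or from 1 is not stated, and they are printed as deposited. Most counts of 10 or more were even (84.7 to 87.4% in technical replicate 1 and 58.0 to 61.2% in technical replicate 2), as they would be if both mates of a pair were counted, so intervals from counts cover counting error only and are too narrow. Depth was 273896 to 326440 reads in regions in technical replicate 1 and 1296355 to 1755015 in technical replicate 2. This is the total within regions, not the sequencing depth.

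Technical replicates of a library were summed. A region's value was its CPM (reads scaled to the library's total in regions) per kb of region, and means and SDs are over the 3 libraries. Dividing by width favours narrow regions. Genes were the 21887 protein-coding genes on chromosomes 1 to 19, X and Y of a RefSeq table of GRCm38.p6, which shares its coordinates with mm10. The table holds no strand, so the planned windows around transcription start sites were replaced by windows around both ends of the gene span. A gene's value was the highest region value within 5 kb of either end, and genes that share a region share a value. Of the 242 list entries, Mx1 had no entry among these genes.

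Before the data were examined the tests, the alternatives, the gene lists and the rule for naming genes were fixed. The rule named Ikzf2, Hoxa9, Meis1, Myc, Myb, Cebpa, Cebpb, Cebpd, Cebpe and Spi1, the 3 highest and the lowest member of each list with a region, the 10 highest genes and the nearest genes of the 10 highest regions. Some genes that the rule names are not reported here. The 9 lists were MLL-AF9 and self-renewal, myeloid differentiation, Ikaros family and NuRD, lymphoid, erythroid and megakaryocytic, survival and cell cycle, inflammatory and interferon, housekeeping, and non-blood tissue. Bcl11a stood in the self-renewal and erythroid lists, and Tfrc in the erythroid and housekeeping lists. Each list's share of genes in the top 10% was compared with that of all other genes by a two-sided Fisher exact test with Benjamini-Hochberg adjustment over the 9 lists, with the housekeeping list, and with 10000 random lists. Genes are not independent where they share regions. The share of regions within 1 kb of a gene end was compared between the top 10% of regions and the rest by a two-sided Fisher exact test, with 95% Wilson intervals.

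Counts were tested with edgeR 4.0.16 (R 4.3.3; filterByExpr at its defaults, TMM, glmQLFit and glmQLFTest, adjusted p under 0.05) between technical replicates with the library as a block, and between libraries with the technical replicate as a term. DESeq2 1.42.0 was an alternative. The block follows the labels, which make both technical replicates part of the same CUT&RUN. Their correlation (0.18 to 0.21) lay above that between libraries (-0.02 to 0.03). The chi-square per degree of freedom was 2.05 to 2.10 between technical replicates of a library, 2.05 to 2.07 between libraries in technical replicate 1 and 3.25 to 3.42 between libraries in technical replicate 2. Technical replicates were summed and counted as 1 sample in means and SDs, although 71 regions differed between them. Correlations used log2 of CPM plus 0.5. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

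The tests were tried on simulated data. For edgeR all simulated counts were even, with the same dispersion for all regions and the same mean profile for all libraries. In the data many counts were odd and libraries hardly correlated, so the recovery rates hold for the simulated setting only. With 200 of 27452 regions changed, edgeR recovered 0% of 2-fold and 23% of 4-fold changes between technical replicates and 0% and 5% between libraries, with 0 false calls in either. This first simulation recovered little, so a second with larger folds was added. For technical replicates it recovered 0%, 34%, 90% and 100% at 2, 4, 8 and 16-fold, with 5 false among 117 calls. For libraries it recovered 0%, 14%, 84% and 100%, with 0 false among 99 calls. For the list test on 21887 genes, 20 of 20 lists of 30 genes raised 4-fold were called. So were 2 of 20 unchanged lists, which were drawn from genes with a region. In the data the lowest region value was 25.6 CPM per kb and the threshold of the top genes 101.8. A 4-fold rise therefore lifts nearly any gene with a region past the threshold. The 20 of 20 thus follows from the size of the rise and does not show whether smaller differences would be called. The location test called 0 of 20 sets of shuffled values.

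Other settings fixed beforehand were the low-count filter, scaling by total reads, DESeq2, the model without the block or term, leaving out each library, values not divided by width, a 1-kb window, the nearest gene within 50 kb, the sum over the window, leaving out the top 0.1% of regions with the mitochondrial and Y regions, each technical replicate alone, top 5% and 20%, genes with a region as background, and a 5-kb window for location. Regions of 200 bp or wider only, halved counts, and leaving out chromosome 4 were chosen after seeing the data. The planned share of regions with the Ikaros core and other motifs was not run, since no genome sequence was used here. The comparison of peak lists was planned only for files of peaks per sample and did not apply.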

Results

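Binding of IKZF2 (Helios), a zinc-finger transcription factor of the Ikaros family, was profiled by CUT&RUN in RN2 cells, a mouse leukaemia line on a C57BL/6 background driven by the MLL-AF9 fusion and a mutant NRAS. In CUT&RUN an antibody directs a protein A-tethered nuclease to its target in permeabilised cells, and the released DNA fragments are sequenced. The cells had been transduced with murine IKZF2 and a red fluorescent marker, sorted and cultured before the assay. The series title places the work in a study of how IKZF2 acts on self-renewal and on the myeloid differentiation program of leukaemic stem cells. The labels describe 10 samples, of which 6 used the anti-IKZF2 antibody (3 CUT&RUN libraries, each with 2 technical replicates) and 4 used a control antibody. The 4 control antibody samples were not analysed here, so signal was compared only among genes and regions within the same libraries.

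Reads had been counted over 151133 regions with a median width of 109 bp (range 90 to 1366 bp). Technical replicate 1 held 299742 reads in library 1, 273896 in library 2 and 326440 in library 3, and technical replicate 2 held 1375495, 1296355 and 1755015. Technical replicate 2 was thus 4.59, 4.73 and 5.38 times as deep. The median region held 2 reads in each of the shallow samples and 8, 7 and 10 in the deep ones, and 37.5%, 41.4% and 34.5% of regions held no read in the shallow samples. Technical replicates of a library were summed, which gave 3 values per region or gene with totals of 1675237, 1570251 and 2081455 reads. Nothing in the labels says that the 3 libraries came from separate cultures, so the SD between them may be technical.

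The first question was where in the genome the strongest signal lay. The 10% of regions with the highest signal lay near the ends of protein-coding genes more often than the other regions did: 25.1% of them (3800 of 15114; 95% Wilson interval 24.5 to 25.8%) lay within 1 kb of a gene end, against 5.23% (7115 of 136019; interval 5.11 to 5.35%) of the rest. The odds ratio was 6.08, with a two-sided Fisher exact p below 1e-300. The share was 4.35% in the lowest decile, 7.73% in the ninth and 25.1% in the highest, and it reached 55.2% among the top 1% of regions. Ranked within single libraries, the top 10% of regions had 13.5%, 17.7% and 13.9% near gene ends (mean 15.0% ± 2.3, SD, n = 3), against 6.52%, 6.05% and 6.48% of the other regions. The annotation used gives no strand, so gene starts and gene ends were not told apart.

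**Figure D1:**
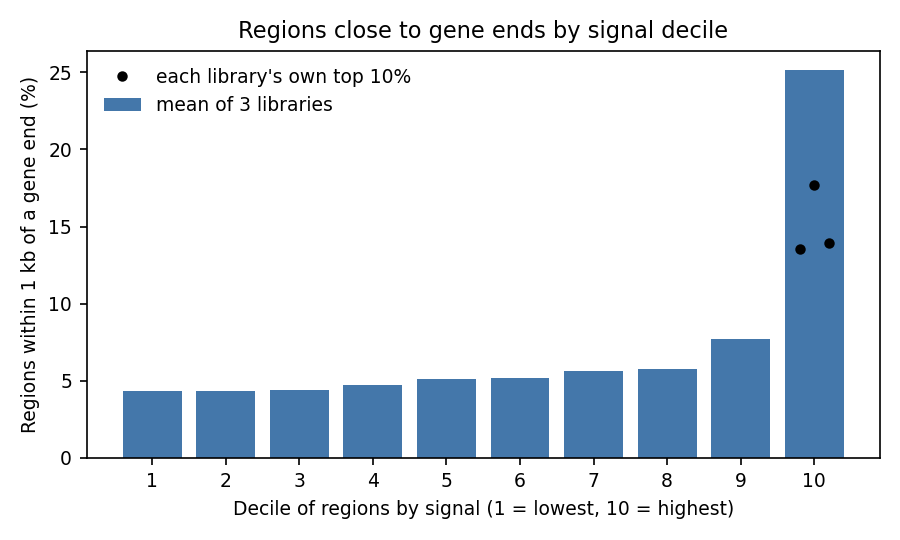
Share of regions within 1 kb of either end of a protein-coding gene (y axis, %) in each decile of regions ranked by mean signal of 3 libraries (x axis, bars); points give the top 10% of regions ranked within each library. The bars stand between 4.31% and 7.73% in deciles 1 to 9 and at 25.1% in decile 10, and the points lie at 13.5%, 17.7% and 13.9%.

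Regions that ranked in the top 10% in all 3 libraries lay at gene ends most often. There were 969 of them, 6.42 times the 151 that independent rankings would give, and 57.7% lay within 1 kb of a gene end. Of the 2461 regions that did so in 2 libraries 40.6% lay there, of the 37489 that did so in a single library 8.39%, and of the 110214 that did so in none 5.63%. The 2461 regions were 0.604 times the 4077 that independent rankings would give, so the 3430 regions shared by 2 or more libraries were fewer than the 4228 given by chance.

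The second question was whether genes tied to the study's subject carried more signal at their ends than other genes. None of the 9 gene lists fixed before the data were examined passed after adjustment for a share of strongly marked genes unlike that of other genes. A low share could not have passed in lists of these sizes. In the longest list, 0 of 35 members gave an unadjusted Fisher exact p of 0.109. A gene's signal was the highest value, in counts scaled to the library total (CPM) per kb of region, among regions within 5 kb of either gene end. Of 21887 protein-coding genes 16133 (73.7%) had such a region, their median signal was 58.8, and 1614 genes at or above 101.8 made up the top 10%. Of these, 301 were in the top 10% in each of the 3 libraries.

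In the list of MLL-AF9 targets and self-renewal genes, 1 of 25 members (4%) was in the top 10% of genes, against 7.38% of other genes (Fisher exact adjusted p = 1). That member was Men1, which encodes the MLL cofactor menin, at 130 ± 32.4 (SD, n = 3; 61.1 in technical replicate 1), with its region on chromosome 19 at 6334837 to 6335050, overlapping a gene end. Dot1l, a histone H3 methyltransferase, stood at 87.4 ± 34.3 (50.1 within 1 kb of a gene end) and Pbx3, a HOX cofactor, at 80.1 ± 32.0. The homeobox gene Hoxa9 stood at 59.1 ± 26.4 (110 in technical replicate 1), its cofactor Meis1 at 73.7 ± 38.8 and Myb at 67.2 ± 18.2. Myc stood at 63.6 ± 45.0, at 19.5 in technical replicate 1 and at 38.8 without library 3. Sox4 was the lowest member with a region, at 44.1 ± 18.3. Hoxa9 and Hoxa10 drew their value from the same region.

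In the list of myeloid differentiation genes, 1 of 34 members (2.94%) was in the top 10%, against 7.38% of other genes (Fisher exact adjusted p = 0.924). Ranked within libraries 1, 2 and 3 the share was 14.7%, 2.94% and 5.88%. Cd68, a lysosomal glycoprotein of macrophages, stood at 166 ± 51.3, with its region on chromosome 11 at 69666181 to 69666302, 11 bp from a gene end. The immediate early gene Egr1 stood at 99.2 ± 18.8. Spi1, which encodes the myeloid transcription factor PU.1, stood at 86.4 ± 10.5. The C/EBP factors stood at 55.5 ± 16.2 (Cebpa), 48.5 ± 18.3 (Cebpb), 45.8 ± 19.8 (Cebpd) and 84.6 ± 12.7 (Cebpe), with 34.1 for Cebpa and 82.5 for Cebpb in technical replicate 1. Cd14, a co-receptor for bacterial lipopolysaccharide, was lowest at 33.2 ± 18.7 (11.9 in technical replicate 1). Ikzf2 itself stood at 47.8 ± 23.9, from 51 reads in a region on chromosome 1 at 69689001 to 69689211, 1650 bp from a gene end. None of Ikzf2, Hoxa9, Meis1, Myc, Myb, Spi1 and the 4 C/EBP genes was in the top 10% in all 3 libraries.

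The list of Ikaros family and NuRD genes had the highest share, 5 of 20 members (25.0%; 95% Wilson interval 11.2 to 46.9%) against 7.36% of other genes. Its unadjusted Fisher exact p was 0.0132 and its adjusted p over the 9 lists 0.119, so it did not pass. The NuRD subunit genes Gatad2a (139 ± 23.4) and Gatad2b (119 ± 41.9) and the Ikaros family gene Ikzf4 (121 ± 61.9) led it, although Ikzf4 fell to 43.7 within 1 kb of a gene end and to 70.3 with regions given to the nearest gene. The other members in the top 10%, named after their values were seen, were Mta2 at 118 ± 54.8 and Sin3a at 109 ± 7.79. None of the 5 was in the top 10% in each of the 3 libraries. Ikzf3 was lowest at 45.4 ± 33.4 (78.3 in technical replicate 1).

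Among genes of survival and the cell cycle, 4 of 26 (15.4%) were in the top 10% (Fisher exact adjusted p = 0.362). Trp53, which encodes the tumour suppressor p53, stood at 167 ± 33.7 and its pro-apoptotic target Bbc3 at 158 ± 57.6, and both were in the top 10% in 3 of 3 libraries. The cyclin-dependent kinase gene Cdk1 stood at 113 ± 61.5 and Bcl2l11 at 113 ± 47.5 (56.1 within 1 kb of a gene end, 190 in technical replicate 1). The proliferation marker Mki67 was lowest at 43.9 ± 23.0 (79.2 with the nearest gene, 16.9 in technical replicate 1). This list passed when signal was summed over the window (26.9%, adjusted p = 0.0199) and when technical replicate 1 alone was used (30.8%, adjusted p = 0.00363), while technical replicate 2 alone gave 11.5% (adjusted p = 1). Of inflammatory and interferon genes, 3 of 22 (13.6%) were in the top 10% (adjusted p = 0.491). They were Stat3 at 171 ± 14.4, the NF-κB subunit gene Rela at 133 ± 57.2 and Tnf at 109 ± 15.3. Stat3 stood at 52.3 without the top 0.1% of regions and at 299 in technical replicate 1 against 144 in technical replicate 2. Rela stood at 90.4 in technical replicate 1 and was in the top 10% in 2 of 3 libraries. Tnf stood at 75.4 in technical replicate 1 and was in the top 10% in 0 of 3 libraries. Oas1a was lowest at 42.2 ± 38.5.

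None of the lists of other lineages and of reference genes passed for its share of the top 10% either, and a low share could not have passed. Of lymphoid genes, 1 of 30 (3.33%) was in the top 10% (Fisher exact adjusted p = 0.929). This was the recombinase gene Rag2 at 108 ± 59.7, which stood at 46.5 with regions given to the nearest gene and at 41.8 in technical replicate 1. It was followed by Cd3g at 97.6 ± 24.4 (53.5 with the nearest gene, 59.0 in technical replicate 1, 42.3 on regions of 200 bp or wider) and Notch3 at 76.4 ± 12.2 (131 in technical replicate 1). Tcf7 was lowest at 35.0 ± 13.2 (69.4 with the nearest gene). Of erythroid and megakaryocytic genes, 1 of 24 (4.17%) was (adjusted p = 1), namely the erythroid factor Klf1 at 119 ± 20 (73.1 with the nearest gene), followed by Itga2b at 98.1 ± 20.9 (59.2 within 1 kb) and Zfpm1 at 96.9 ± 36.3. Vwf was lowest at 48.7 ± 22.9, but stood at 209 with the nearest gene. Of housekeeping genes, 2 of 25 (8%) were (adjusted p = 0.929). Sdha, a succinate dehydrogenase subunit gene, stood at 112 ± 8.89 (67.5 with the nearest gene, 64.7 in technical replicate 1) and B2m at 91.7 ± 25.8. Ywhaz was lowest at 49.1 ± 26.2 (106 with the nearest gene, 18.7 in technical replicate 1). Of genes of non-blood tissues, 0 of 35 were (95% Wilson upper bound 9.89%; adjusted p = 0.362), and Nphs1 (102 ± 52.7), Myh6 (81.7 ± 38.6; 52.2 within 1 kb and with the nearest gene) and Gfap (68.8 ± 33.5) led that list. Krt5 was lowest at 36.3 ± 21.4 (0 in technical replicate 1). No list passed against the housekeeping list in its share of the top 10% (lowest Fisher exact adjusted p = 0.857). Single list members depended on how a gene was valued: of the 18 in the top 10% of genes, Trp53 alone stayed there in all 12 other ways of valuing genes, and Rag2 stayed in 4. The mean signal of the members, with genes lacking a region at 0, lay at percentile 84.5 of 10000 random lists of the same size for the self-renewal list, 98.3 for myeloid, 98.9 for Ikaros and NuRD, 38.7 for lymphoid, 73.4 for erythroid, 99.9 for survival, 99.5 for inflammatory, 98.2 for housekeeping and 2.73 for non-blood genes. By this mean several lists, housekeeping included, lay near the upper end of random lists and the non-blood list near the lower end. Since genes without a region count as 0, the percentiles mix the presence of a region with its signal. A region was present for 33 of 34 myeloid and 24 of 35 non-blood genes, against 73.7% of all genes. No share of the top 10% passed in the main setting, and no p-value was taken from these percentiles.

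**Figure D2:**
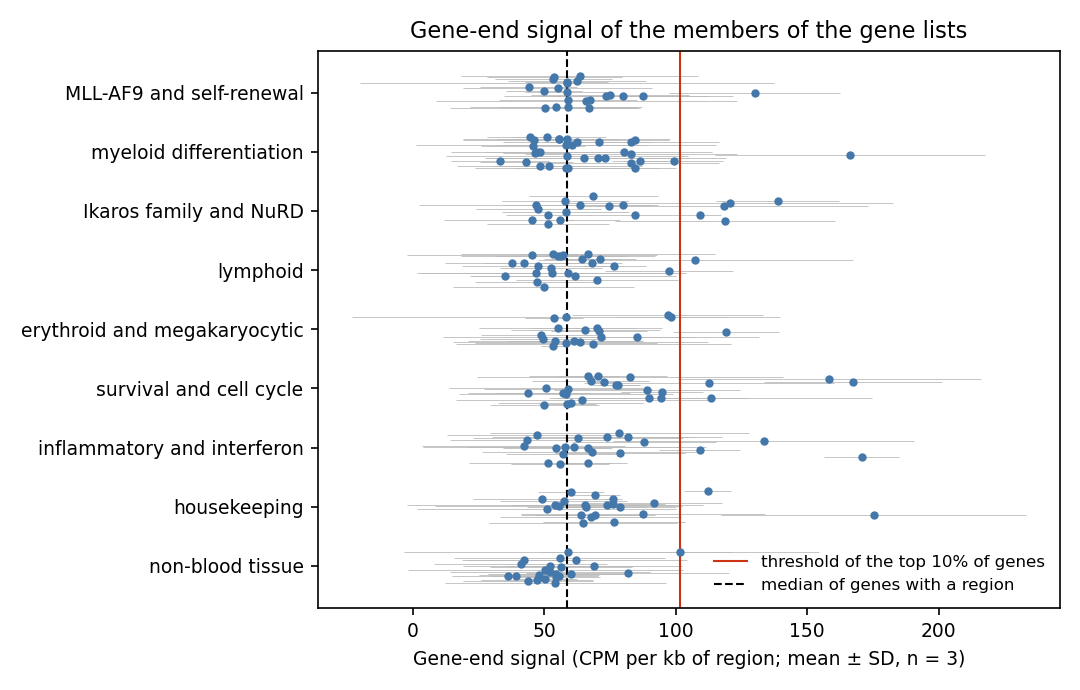
Signal at the gene ends (x axis, CPM per kb of region) of the members of the 9 gene lists that have a region, as mean and SD of 3 libraries; vertical position within a list is only spread for display. The solid line marks 101.8, the threshold of the top 10% of genes, and the broken line the median of 58.8; most members lie below the solid line in each list.

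The 10 genes with the highest signal belonged to none of the lists. Ifna13, an interferon alpha gene, stood at 464 ± 35.4 (SD, n = 3), from a region on chromosome 4 at 88641119 to 88641265. Taco1, a mitochondrial translation factor gene, stood at 462 ± 3.11, from a region on chromosome 11 at 106066771 to 106066875 inside the gene span. Psmd12, which encodes a proteasome subunit, stood at 372 ± 187, from chromosome 11 at 107479356 to 107479446, 82 bp from a gene end. Sdhc stood at 371 ± 104, and Pcnx3 and Sipa1 shared a region at 280 ± 50.7. Fgd2 (272 ± 50.8), Polr1e (258 ± 79.1) and A930018P22Rik (253 ± 58.6) followed. Without the top 0.1% of regions Ifna13 stood at 89.2, Taco1 at 77.2, Psmd12 at 51.1, Pcnx3 at 106, Sipa1 at 133, Fgd2 at 77.5, Polr1e at 49.8 and A930018P22Rik at 51.4. On regions of 200 bp or wider Ifna13 stood at 89.2, Pcnx3 at 106, Fgd2 at 77.5, Polr1e at 40.8 and A930018P22Rik at 42.1. Ifna13 stood at 69.9 within 1 kb of a gene end and Pcnx3 at 106 with the nearest gene. In technical replicate 1 the values were 945 for Ifna13, 1311 for Taco1 (285 in technical replicate 2), 67.8 for Psmd12 and 172 for Fgd2. The regions of these genes were 90 to 146 bp wide and thus belong to width classes in which signal was negatively correlated between libraries.

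The 10 regions with the highest signal all lay 8055 bp or more from a nuclear gene end or on the mitochondrial genome. The highest was on the mitochondrial genome at 15853 to 16272, with 3736 ± 824 CPM per kb. It was followed by a region on chromosome 6 at 10186388 to 10186479 (2285 ± 1773; nearest gene Nxph1) and by a region on chromosome Y at 90767828 to 90767992 (1878 ± 400; nearest gene Gm52481). The others were on chromosome 6 at 132463719 (1322 ± 1175; Gm8882), chromosome 18 at 73533432 (1058 ± 62.7; Mex3c), chromosome 16 at 77946898 (645 ± 123; Cxadr), chromosome 4 at 3064448 (619 ± 184; Vmn1r2), chromosome 19 at 61267007 (587 ± 115; Csf2ra), chromosome 9 at 19575437 (564 ± 380; Olfr854) and chromosome Y at 90782099 (556 ± 111; Gm52481).

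The technical replicates of a library differed at regions near gene ends and at narrow regions far from genes. edgeR's quasi-likelihood test with the library as a block called 71 of 27452 tested regions at an adjusted p under 0.05, with 38 higher in technical replicate 2 and 33 higher in technical replicate 1. Those higher in technical replicate 2 had a median width of 340.5 bp, and 21 of 38 (55.3%) lay within 1 kb of a gene end. Of those higher in technical replicate 1, with a median width of 104 bp, 2 of 33 (6.06%) did (Fisher exact p = 7.94e-06), and 18 (54.5%) lay over 50 kb from a gene end. Across all 27452 tested regions the median width was 170 bp, 16.7% lay within 1 kb of a gene end and 28.6% over 50 kb away. The region by Psmd12 was higher in technical replicate 2 by 4.74 ± 0.79 on the log2 scale (SE; edgeR adjusted p = 2.57e-06), with 0, 2 and 0 reads in technical replicate 1 and 29, 78 and 67 in technical replicate 2. The region at an end of Rassf4 was higher by 3.29 ± 0.58 (edgeR adjusted p = 1.57e-05) and the region at an end of Srgap2 by 1.45 ± 0.30 (edgeR adjusted p = 9.14e-04). In the other direction the region on chromosome 16 at 77946898, 354212 bp from the nearest gene end, fell by 5.49 on the log2 scale (SE 0.28; edgeR adjusted p = 1.34e-78), from 124, 136 and 100 reads to 3, 3 and 25. The division into higher and lower depended on scaling: with total reads in place of TMM 55 regions were called, 9 higher and 46 lower in technical replicate 2, and DESeq2 called 56, 14 higher and 42 lower. The location of called regions was compared under TMM only. Without library 1, 2 or 3 the count was 18, 0 or 8. There 702 of 14407, 819 of 20751 and 849 of 17301 tested regions had an edgeR unadjusted p under 0.05. These shares lie below 0.05, no more than tests without any difference would give.

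Between the 3 libraries edgeR's test, with the technical replicate as a term, called 4 of 27452 regions (1193 at an unadjusted p under 0.05). The 1193 are a share below 0.05, no more than tests without any difference would give. Each library is a single CUT&RUN, so this test sets differences between libraries against the spread of their technical replicates only. The chromosome 6 region at 10186388 held 316 and 302 reads in library 2, against 104 and 112 in library 1 and 100 and 111 in library 3 (edgeR adjusted p = 5.79e-15). The chromosome 6 region at 132463719 (edgeR adjusted p = 1.82e-14) and a region on chromosome 17 at 4626171 to 4626595 (edgeR adjusted p = 2.21e-04; nearest gene Arid1b, 367702 bp away) were also highest in library 2. The mitochondrial region was lower in library 2 than in library 1 (log2 difference -0.77, edgeR adjusted p = 3.74e-11). Both chromosome 6 regions and the mitochondrial region also differed between technical replicates. Technical replicate 2 differed from 1 by -1.58 (10186388), -1.98 (132463719) and 0.81 (mitochondrial) on the log2 scale (edgeR adjusted p = 4.91e-17, 3.28e-18 and 4.79e-20). DESeq2 also called 4 regions. Without library 1 the count was 4. Without library 2 or 3 it was 0, with 1122 of 20751 and 956 of 17301 tested regions at an edgeR unadjusted p under 0.05. With the library alone in the model edgeR called 0 regions, with 1507 of 27452 at an unadjusted p under 0.05. The shares in these fits with 0 calls lay just above 0.05.

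Agreement between libraries rose with the width of the region, but wider regions also held more reads and lay more often at gene ends. The median was 26 reads up to 100 bp and 127.5 over 400 bp, and 5.03% and 35.3% lay within 1 kb of a gene end. Width was not separated from these. CPM was not divided by width here, and the narrowest class ran from 90 to 100 bp but the widest from over 400 to 1366 bp. Where reads follow width, a wide span of widths within a class can by itself raise r, which was not tested. Across all regions Pearson's r of log2 CPM was 0.18 to 0.21 between technical replicates of a library and -0.02 to 0.03 between samples of different libraries. These correlations run across regions, which are not independent replicates. Between libraries with technical replicates summed, the mean r of the 3 pairs was -0.28 for the 49087 regions up to 100 bp wide. It was -0.21 over 100 and up to 150 bp, -0.15 over 150 and up to 200 bp and 0.079 over 200 and up to 300 bp. For the 430 regions over 400 bp it was 0.66. Between technical replicates it was 0.11 at up to 100 bp and 0.40 over 400 bp, but these pairs join a shallow and a deep sample, so the 2 sets of values are not matched in depth.

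**Figure D3:**
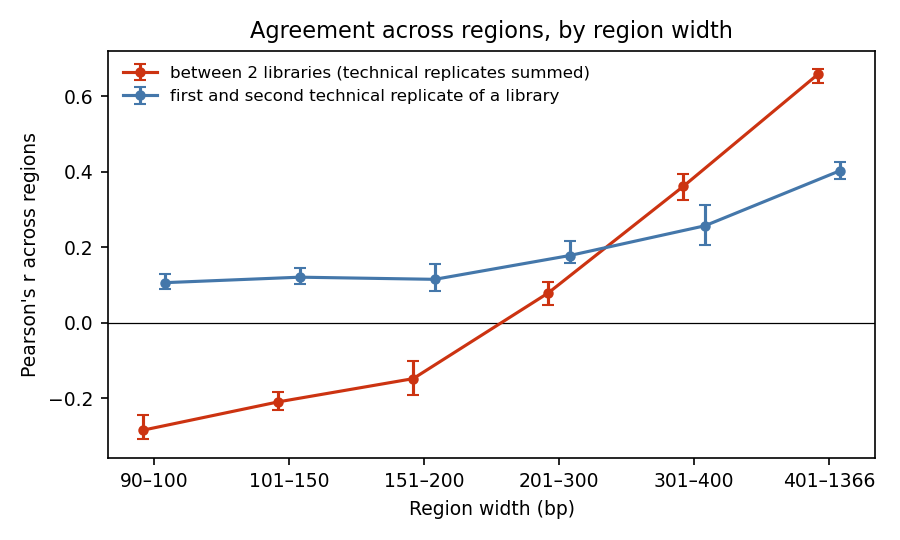
Pearson's r across regions of log2 CPM (y axis) by region width (x axis, bp), between libraries with technical replicates summed (3 pairs) and between technical replicates of a library (3 pairs); points are means and bars run from the lowest to the highest pair. Between libraries the mean runs from -0.28 in the narrowest class to 0.66 in the widest.

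Regions were unevenly spread over the chromosomes. The part of chromosome 4 from 3 to 60 Mb held 155 ± 60.9 regions per Mb (SD over 57 bins of 1 Mb), against 59.8 ± 30.2 in the rest of chromosome 4 and 60.4 ± 29.7 on the other autosomes, a ratio of 2.55. Of the 355 genes that start in this segment, 84 (23.7%) were in the top 10% of genes, against 7.52% of other autosomal genes (two-sided Fisher exact p = 1.25e-20). Polr1e was the member of the 10 leading genes that lay there. The segment and its boundary were chosen after the counts along the chromosome had been seen. A gene's value is the highest among its regions, so the many regions of the segment can by themselves raise its share of top genes. The Fisher test on these genes is thus no separate result. Chromosome X held 3.17 regions per Mb, against 52.3 to 74.2 on autosomes other than chromosome 4.

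**Figure D4:**
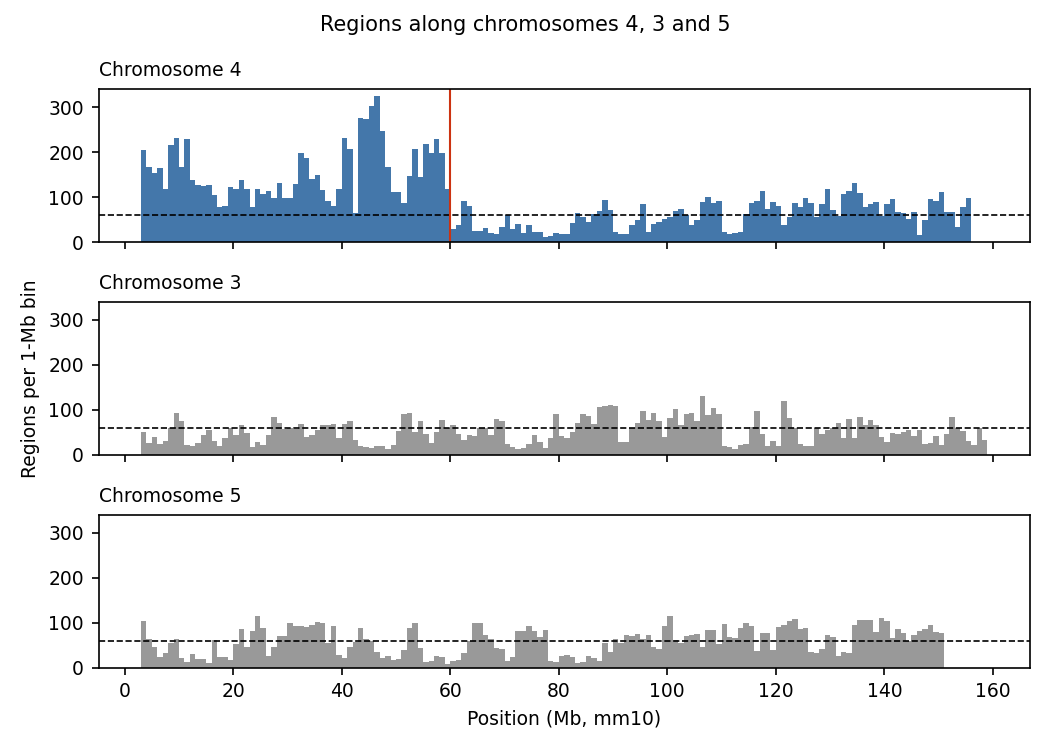
Number of regions in each 1-Mb bin (y axis) along chromosomes 4, 3 and 5 (x axis, Mb, mm10); the broken line is the autosomal median of 60 regions per bin and the solid line marks 60 Mb on chromosome 4. All 57 bins of chromosome 4 before that line lie above the median.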

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

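Tests on halved counts, on regions of 200 bp or wider, without chromosome 4 and of gene families among genes with a region were chosen after seeing the data, and the other alternatives were planned. The location share kept its direction and its side of the threshold in all 8 alternatives, between 16.4% and 38.1%. Of 135 comparisons of a gene list under an alternative, 133 stayed on the same side of the threshold. The exceptions were the survival and cell cycle list with the sum over the window (26.9%) and with technical replicate 1 alone (30.8%); over its alternatives the share ran from 3.85% to 34.6% and the adjusted p from 0.00363 to 1, and the cause was not tested. The Ikaros and NuRD list ran from 10% to 30%, with adjusted p from 0.0700 to 0.820. Of the values of named genes under alternatives in the same unit, 485 moved by less than 1 SD and 109 by more. Cases in which a gene lost its region under the alternative, and so had no value, are not counted. Bbc3, Klf1, Rag2, Tnf and Sdha, for example, had no region within 1 kb of a gene end. The odds ratio of gene families fell from 43.5 to 19.3 among genes with a region, since most receptor genes had none.

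Between technical replicates the 71 calls became 46 with no low-count filter and 46 without the replicate block (5 higher and 41 lower in technical replicate 2, with 9743 regions tested). Leaving out a library gave 0 to 18 calls, with fewer samples. Total reads, DESeq2 and halved counts gave 55, 56 and 72. Between libraries the 4 calls became 0 with the library alone in edgeR's model (1507 at an unadjusted p under 0.05; DESeq2 on the planned model called 4) and 7 with halved counts, where 2209 regions were tested. Leaving out a library gave 0 to 4. The cause was not tested. On simulated data with the totals of these samples, all counts even and a shared profile, 2-fold changes were not recovered. Depth itself was not varied. The motif comparison was not run.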

Other observations

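The tests on gene families, on the presence of any region, on width and on chromosome 4 in this part were chosen after seeing the data, and so were the tests of the explanations, except those of promoters used in most cells and of gene ends on chromosome 4, whose predictions were written before their results were seen.

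Gene families differed in signal on the autosomes. Families were defined by the start of the gene symbol alone, so a family can hold genes with such names that are not subunits or members. Of 50 proteasome subunit genes, 11 (22.0%) were in the top 10% of genes, against 7.77% of other genes (two-sided Fisher exact adjusted p = 0.00412 over 9 families). Subunits of NADH dehydrogenase reached 17.0% (8 of 47, adjusted p = 0.0609), cytosolic ribosomal proteins 13.8% (13 of 94, adjusted p = 0.0746), mitochondrial ribosomal proteins 11.5% (9 of 78, adjusted p = 0.230), zinc-finger genes named Zfp 10.3% (40 of 388, adjusted p = 0.0886) and solute carriers 7.18% (26 of 362, adjusted p = 0.766), and these did not pass. Olfactory receptor genes were far below other genes (3 of 1104, 0.272%, adjusted p = 1.94e-34), as were vomeronasal receptor genes (3 of 354, 0.847%, adjusted p = 1.19e-08), while 0 of 53 keratin genes were in the top 10% (adjusted p = 0.0609). Most receptor genes had no region within 5 kb of a gene end and so no value: 418 of 1104 olfactory genes had one (37.9% against 79.7% of other genes, adjusted p = 1.72e-185), as did 146 of 354 vomeronasal genes (41.2% against 78.1%, adjusted p = 8.01e-49).

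A region within 5 kb of a gene end, whatever its signal, was more common among the myeloid differentiation genes than among other autosomal genes: 33 of 34 (97.1%) against 77.4% (Fisher exact adjusted p = 0.0290 over 9 lists). The gene without such a region was Csf2ra. Inflammatory genes had 21 of 22 (95.5%, adjusted p = 0.186), survival and cell cycle genes 24 of 26 (92.3%, adjusted p = 0.290), housekeeping genes 20 of 22 (90.9%, adjusted p = 0.387), Ikaros and NuRD genes 17 of 19 (89.5%, adjusted p = 0.418), self-renewal genes 22 of 25 (88.0%, adjusted p = 0.431), erythroid genes 19 of 22 (86.4%, adjusted p = 0.501), lymphoid genes 24 of 29 (82.8%, adjusted p = 0.657) and non-blood genes 23 of 34 (67.6%, adjusted p = 0.387). Whether the myeloid share differs from the housekeeping share was not tested.

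A candidate explanation for the family pattern is that signal follows promoters used in most cells. The 4 widely used families together had 41 of 269 genes (15.2%) in the top 10% of genes, against 6 of 1458 (0.412%) of the receptor genes, an odds ratio of 43.5, as this explanation predicts. The families are those of the pattern itself, so this odds ratio restates it and is no separate support. Part of that ratio is the presence of a region (239 of the 269 genes against 564 of the 1458), and among genes with a region 17.2% and 1.06% were in the top 10%, an odds ratio of 19.3. Why receptor genes lack regions, reads shared between paralogs included, was not tested. The housekeeping list had 8% in the top 10% against 7.37% of other genes (4%, 4% and 24% in libraries 1, 2 and 3). Its mean signal, with genes lacking a region at 0, lay at percentile 98.2 of random lists, so this list does not decide on the explanation. Without the control antibody samples signal of open chromatin and signal of IKZF2 stay unseparated.

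Over all regions, technical replicates of a library correlated more than libraries did. The lowest correlation within a library exceeded the highest one between a first and a second technical replicate of different libraries by 0.161. Regions up to 100 bp wide were negatively correlated between libraries (highest -0.24), and the leading library held a median 51.0% of the scaled reads, against 46.2% under equal sampling, which is consistent with regions having entered the set for a high count in a single library. Choosing regions in that way can raise correlations within a library even on counting noise alone, which was not simulated here. So neither the gap nor the correlation within libraries among these regions (lowest 0.0904) decides between the remaining candidates. These are counting noise over a shared profile and few DNA fragments sequenced in both technical replicates, and both stay open. No biological explanation was tested.

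The excess of regions on chromosome 4 from 3 to 60 Mb may have several sources. More gene ends there are argued against, since regions over 50 kb from any gene end were 2.92 times as dense as elsewhere, and the segment held 6.23 genes per Mb against 8.63. A few dense clusters are argued against, since 100% of the 1-Mb bins were above the autosomal median. Extra copies of the segment in these cells stay open after 2 tests, neither of which decides: each library's own top 10% of regions held a 2.73 to 3.08-fold excess, which the number of regions largely fixes, and wide regions at gene ends had a median value at least 0.896 times that elsewhere in each library, but were 2.66 times as frequent per gene, so that weaker ones can lower the median. Reads outside the regions were not used here.

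Between technical replicates, 71 regions passed the threshold, and 1 of the 10 splits of the 6 samples, the real one, gave as many; the highest other count was 0. Of the 10, 4 part the technical replicates of each library, the real one among them. The other 3 of these called 0 of 27452 regions in edgeR, with 187 to 236 at an unadjusted p under 0.05. The remaining 6 keep both technical replicates of a library together and tested 82454 regions, so they are no match. Both sets are too few for a share under 0.05.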
